A study of Canis lupus familiaris with 4 samples.

How the data were processed

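RNA was measured by poly(A)-selected RNA sequencing in MDCKII cells, a canine kidney epithelial cell line that forms a polarised monolayer when it is left confluent. There were 4 libraries in 2 groups of 2: cells grown for 7 days, and cells grown for 7 days, detached and plated again for 2 h before harvest. Per the labels' protocols, messenger RNA was captured on oligo(dT) beads, fragmented and copied from random hexamers, and the protocol names no step that marks strand. Whether the counting used strand is not given in the sources used here. Without strand, reads from a gene and from an antisense neighbour would not be told apart. The labels call the libraries of a group biological replicates and do not say whether they came from separate cultures, so the p-values measure the spread between these libraries.

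The count table deposited by the authors holds estimated counts of reads per gene, one column per library, with no pooling of replicates. The deposited values were taken as unnormalised because the file header names them read counts and because the column totals differ between libraries. Estimated counts were whole, within 0.001, in all 4 libraries for 92.1% of the 25759 genes, and 2040 genes had a value that was not whole in at least 1 library. A second table deposited by the authors gives FPKM for the same genes and libraries, to 2 decimals. The submitters' processing notes name CASAVA, HISAT2 2.0.5, FastQC and the CanFam3.1 genome build. The counting tool, the annotation release and any filter are not given in the sources used here. Dividing the deposited counts by the deposited FPKM values and by the library total returned a gene length that differed between libraries. This was measured on 5214 genes with an FPKM of at least 10 and a count above 200 in every library. Relative to day 7 replicate 1, the median offset was -14.5 and -19.3 nt in reseeded replicates 1 and 2 and -18.3 nt in day 7 replicate 2. The FPKM values were therefore taken to rest on an effective length per library. A median does not show that the offset is the same for short and long genes. The length returned for the library in which a gene had its highest FPKM is used below as the length of that gene. It thus depends on which library that was.

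Genes are identified by Ensembl gene IDs (24580) and by IDs that begin with XLOC (1179). Names of that form are given by transcript assembly programs to loci that they build from reads. What the authors did to define these loci is not given in the sources used here. The files do not pair IDs with gene symbols, and 0 IDs matched the RefSeq gene table used for names, which has 43286 genes and carries no Ensembl IDs. The 33 gene lists (821 entries) that had been fixed before the data were examined, which were lists of symbols, could therefore not be tested, and no gene is named here. The rule fixed for named genes had 3 parts. The parts that took genes from the fixed lists, and nuclear envelope and junction genes whatever they showed, need symbols and could not be applied. The remaining part asked for the largest fold changes in each direction among genes with a symbol, an adjusted p below 0.05, a mean of at least 10 CPM over the 4 libraries, and both reseeded libraries on the same side of both day 7 libraries. No gene met it because none has a symbol. Without the symbol condition, a change made after the files had been seen, 909 genes met it, and the 2 with the largest increase and the 2 with the largest decrease are given by their IDs. Coordinates are not used here.

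Estimated counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 12830 genes with at least 99.95% of the counts of each library. Libraries were scaled by the trimmed mean of M-values (TMM), and groups were compared with edgeR 4.0.16 (R 4.3.3) by the robust quasi-likelihood F test without covariates, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are 2 h after reseeding over day 7, and their standard error (SE) is the log2 fold change divided by the square root of the F statistic. Normalised expression is given as TMM-scaled CPM, with the SD over 2 libraries. In place of the symbol lists, XLOC loci and quintiles of gene length were compared, a choice made after the files had been seen. Whether called genes of a class were higher or lower was compared with the other called genes by Fisher's exact test, two-sided and adjusted over 10 classes, which treats genes as independent. XLOC loci and the shortest and longest quintiles were also tested as 3 sets with camera of limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, and with fry.

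The fit was tested on simulated counts for the 12830 genes tested, with the library sizes and trended dispersion of this comparison. edgeR recovered 12% of 100 genes changed 2-fold and 84% of 100 genes changed 4-fold, and called 0 of the unchanged genes. Most of the simulated 2-fold changes were thus missed with 2 libraries per group. The changed genes were drawn from those with a mean of at least 1 CPM. Genes were simulated independently, without deviations that many genes of a library share. The 0 unchanged genes called are therefore not an error rate for the real libraries. The alternatives fixed before the data were examined were other scaling factors, other filters, DESeq2 1.42.0, limma voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, a fit without the robust option, thinning to the smallest library, and leaving out each library in turn. Removing a smooth length trend from each library, leaving out genes with values that were not whole and leaving out XLOC loci were added after the data had been seen. The labels give the same biological replicate numbers, and the same letters A and B, to both groups. They do not say whether these mark a shared culture or day, so the numbers were not used as pairs.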

Results

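The series profiled the messenger RNA of wild-type MDCKII cells as a mature epithelium and soon after the epithelium had been taken apart. Cells grown for 7 days (2 libraries) were compared with cells that had also been grown for 7 days and were then detached and plated again for 2 h (2 libraries). The series title concerns invaginations of the nuclear envelope and the arrangement of chromatin in epithelium, and the comparison asks which transcripts differ between the 7-day cell layer and freshly plated cells. The library totals were 13958380 and 15796647 estimated counts at day 7 and 15754369 and 22181567 after reseeding, for replicates 1 and 2 of each group. Between 14691 and 15090 genes had at least 1 count per library. The most abundant gene took 1.80% to 2.00% of the counts of a library, and the 100 most abundant took 24.0% to 27.0%.

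The 2 groups were separated more widely than the libraries within a group. Across the 12830 genes tested, Pearson's correlation of log2 CPM was 0.970 between the reseeded libraries and 0.969 between the day 7 libraries, against 0.900 to 0.942 between libraries of different groups. These correlations are across genes, which are not independent replicates. The common biological coefficient of variation was 26.5%. Counts differed between the libraries of each group by far more than sampling noise (chi-square per degree of freedom of 71.4 after reseeding and 52.8 at day 7), so no library was taken as another one deposited again. This sets reads against counting noise alone and does not show that the libraries came from separate cultures. Of the 2 day 7 libraries, replicate 1 was closer to the reseeded libraries, with correlations of 0.942 and 0.935, than replicate 2, with 0.910 and 0.900.

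At 2 h after reseeding 724 genes rose and 615 fell relative to the day 7 layer, which is 10.4% of the genes tested (edgeR quasi-likelihood test, adjusted p below 0.05). The median change was 3.53-fold among the genes that rose and 2.98-fold among those that fell. Of the genes that rose, 705 did so at least 2-fold, 294 at least 4-fold, 93 at least 8-fold and 34 at least 16-fold. Of those that fell, 597 did so at least 2-fold, 184 at least 4-fold, 50 at least 8-fold and 17 at least 16-fold. The smallest change that passed was 0.92 on the log2 scale. In all 1339 genes called, both reseeded libraries lay on one side of both day 7 libraries. Among all genes tested this held for 57.7%, against 33.3% by chance. With library size as the only scaling 476 genes rose and 384 fell, and with upper-quartile factors more genes fell (662) than rose (625). The numbers also depended on single libraries. Without day 7 replicate 1 the genes that rose numbered 1515 and those that fell 885. Without day 7 replicate 2 the numbers were 482 and 306. The genes that fell numbered 388 without reseeded replicate 1 and 346 without reseeded replicate 2. limma on log2(FPKM + 1) called 387 higher and 341 lower genes with a mean FPKM of at least 1, and 0 genes without that filter (3191 at an unadjusted p below 0.05).

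**Figure D1:**
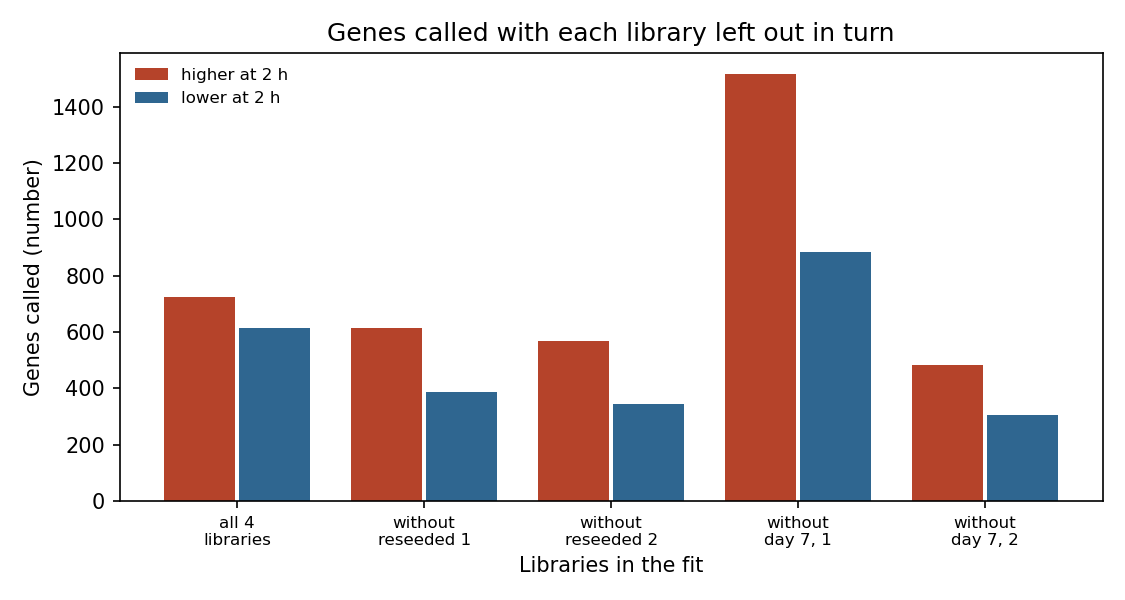
Number of genes called higher or lower at 2 h after reseeding (vertical axis, adjusted p below 0.05) with all 4 libraries and with each library left out in turn. Leaving out day 7 replicate 1 gave 1515 higher and 885 lower genes, and leaving out day 7 replicate 2 gave 482 and 306.

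Called genes were found at all expression levels. The genes that rose took 8.96% and 9.60% of the counts in the reseeded libraries, against 3.43% and 2.58% in the day 7 libraries. The genes that fell took 2.40% and 2.28% after reseeding, against 6.12% and 6.94% at day 7. These shares describe genes that were chosen on the same libraries. Of the 2145 genes with a mean above 100 CPM, 139 rose and 102 fell. Of the 6661 genes between 10 and 100 CPM, 377 rose and 291 fell. Of the 4024 genes below 10 CPM, 208 rose and 222 fell. The split between higher and lower differed from that of the other called genes in this last class (Fisher's exact test, adjusted p = 0.00958) and not in the first (adjusted p = 0.225) or the second (adjusted p = 0.112). Of the called genes, 24 had at most 3 counts over both day 7 libraries, and 13 had at most 3 counts over both reseeded libraries. Their fold changes are fitted values that depend on a prior count and are not bounds.

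The largest increase among genes with a mean of at least 10 CPM was that of ENSCAFG00000030300, which went from 0.20 ± 0.10 CPM (SD, n = 2) at day 7 to 22.0 ± 7.56 CPM (SD, n = 2) after reseeding. Its log2 fold change was 6.72 with an SE of 0.58 (edgeR, adjusted p = 1.63e-06), and its day 7 values rest on 4 and 2 counts. ENSCAFG00000004160 followed, with 0.34 ± 0.01 CPM at day 7 and 24.2 ± 23.5 CPM after reseeding (SD, n = 2). Its day 7 values rest on 5 counts in each library. Its log2 fold change was 6.15 with an SE of 0.93 (edgeR, adjusted p = 0.00495). The 2 reseeded libraries differed for this gene, with 7.64 CPM in replicate 1 and 40.9 CPM in replicate 2. Without reseeded replicate 2 its log2 fold change was 4.48, and limma voom did not call it (adjusted p = 0.0664, against 1.78e-24 to 0.173 over the 20 alternatives). limma on log2(FPKM + 1) did not call it either, with or without a filter (adjusted p = 0.0577 and 0.173). The largest decrease was that of ENSCAFG00000003904, from 58.0 ± 18.0 CPM at day 7 to 1.70 ± 0.89 CPM after reseeding (SD, n = 2). Its log2 fold change was -5.06 with an SE of 0.45 (edgeR, adjusted p = 3.21e-06). ENSCAFG00000005510 fell from 25.9 ± 7.77 CPM to 0.83 ± 0.19 CPM (SD, n = 2), a log2 fold change of -4.94 with an SE of 0.46 (edgeR, adjusted p = 3.31e-06). All 4 genes had whole counts in every library, and their direction was kept under each of the 20 alternatives run. They were chosen among genes whose groups do not overlap, so a change of direction was unlikely from the start. Without a filter on low FPKM values, none of the 4 passed in limma on log2(FPKM + 1), with adjusted p between 0.0648 and 0.173.

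**Figure D2:**
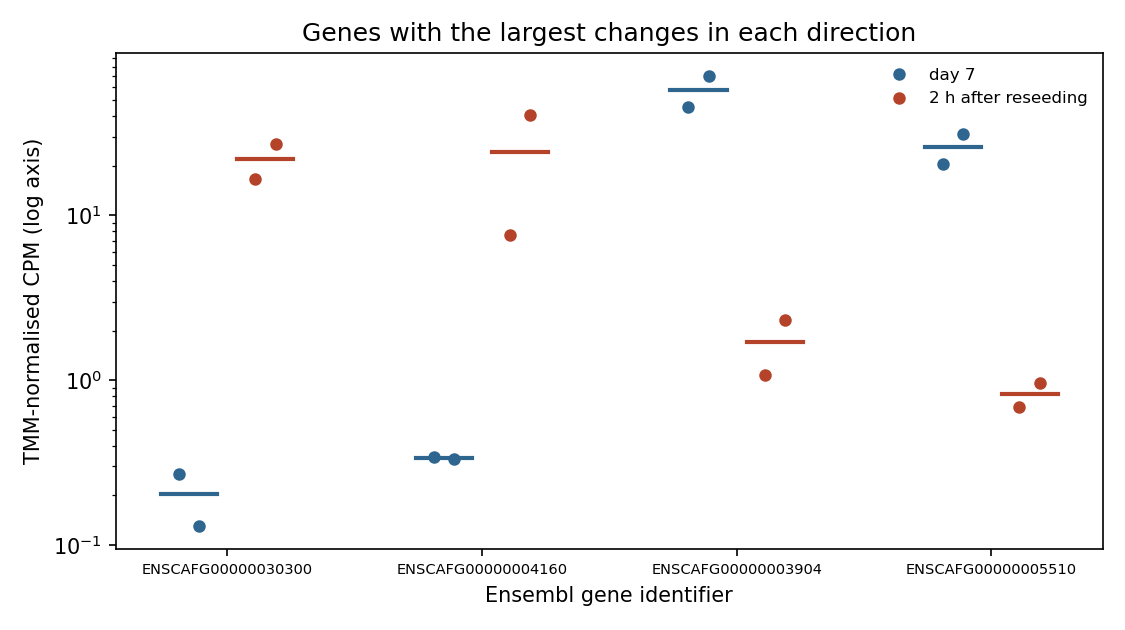
TMM-normalised CPM (log axis) of the 2 genes with the largest increase and the 2 with the largest decrease, in the day 7 and the reseeded libraries. Points are single libraries and bars are means of 2, and the groups do not overlap for any of the 4 genes, which was a condition for their choice.

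Long genes rose more often than short ones, a grouping chosen after the files had been seen. In the longest quintile of genes (effective length above 4044 nt) 226 rose and 111 fell, and the median log2 fold change was 0.17. With a single library left out this median ran from 0.11 to 0.29. In the shortest quintile (below 824 nt) 68 rose and 123 fell, with a median of -0.21. Expression also differed, with a median of 47.4 CPM in the longest and 11.2 CPM in the shortest quintile. Both splits differed from those of the other called genes (Fisher's exact test, adjusted p = 2.35e-07 for each). As sets, the longest quintile was higher and the shortest lower with a preset correlation (camera, adjusted p = 0.00465 and 0.00255), and neither call held with an estimated correlation (adjusted p = 0.336 for both). Neither was called by fry (adjusted p = 0.219 for both), which tests whether the genes of a set move on balance one way. Falling genes did not outnumber rising ones in the shortest quintile without day 7 replicate 2 or without reseeded replicate 2. Rising genes also made up a larger share of all calls in these fits. The median log2 fold change of the shortest quintile was then -0.11 and -0.19, against 0.01 and -0.02 over all genes tested. Without day 7 replicate 1, 468 genes of the longest quintile rose and 127 fell, and 123 of the shortest rose and 215 fell. In the longest quintile 135 rose and 86 fell without day 7 replicate 2, 208 and 83 without reseeded replicate 1, and 147 and 68 without reseeded replicate 2. In the shortest quintile 53 rose and 72 fell without reseeded replicate 1. Removing a smooth length trend from each library takes out such a split by construction, and then left 188 higher and 199 lower genes in the longest quintile and 114 and 95 in the shortest.

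Loci with XLOC identifiers fell more often than genes with Ensembl identifiers. Of 992 XLOC loci tested 59 rose and 107 fell, with a median log2 fold change of -0.31, against 665 and 508 of 11838 Ensembl genes with a median of 0.01. The 2 kinds of identifier differed in this split (Fisher's exact test, adjusted p = 8.08e-07). As a set XLOC loci were lower with a preset correlation (camera, adjusted p = 0.00255), not with an estimated correlation (adjusted p = 0.336), and not by fry (adjusted p = 0.219). Without day 7 replicate 2 the median log2 fold change of XLOC loci was -0.17, against 0.01 for Ensembl genes. XLOC loci thus stayed lower than Ensembl genes, by less than with all 4 libraries. Rising genes made up a larger share of all calls in that fit, and falling XLOC loci did not outnumber rising ones. Without reseeded replicates 1 and 2 in turn 56 and 45 rose and 71 and 64 fell, and without day 7 replicate 1 the numbers were 76 and 111. XLOC loci were less abundant than Ensembl genes, with a median of 3.49 against 26.9 CPM, and took 1.80% and 1.96% of the counts after reseeding and 1.97% and 2.20% at day 7.

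**Figure D3:**
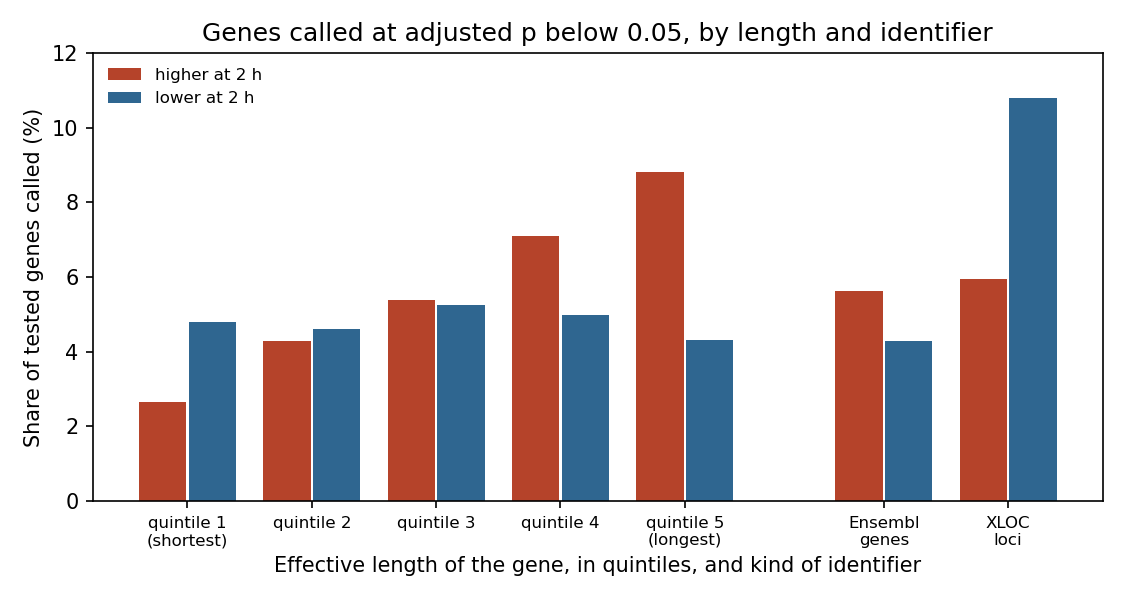
Share of the tested genes called higher or lower at 2 h after reseeding (vertical axis, percent), by quintile of effective length and by kind of identifier. In the longest quintile 8.81% of genes were higher and 4.33% lower, and among XLOC loci 5.95% were higher and 10.8% lower.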

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

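Removing the length trend and leaving out genes with counts that were not whole or XLOC loci were chosen after the data had been seen. Over 20 alternatives, 54 of 80 values of the 4 counts of genes (higher, lower, and each at least 2-fold) stayed within 1.5 times the reported count, and 26 did not. With library size as the only scaling, 476 genes were higher and 384 lower, and 384 were at least 2-fold lower. Without a filter 1230 genes were higher, 1060 of them at least 2-fold. In limma on log2(FPKM + 1) with a mean FPKM of at least 1 there were 387 higher and 341 lower genes, and on log2(FPKM + 0.1) there were 349 and 279, all at least 2-fold. On log2(FPKM + 1) without a filter limma called 0 genes, with 3191 at an unadjusted p below 0.05, against 1339 called by edgeR and 1495 by DESeq2 on counts. Leaving out each library in turn gave 482 to 1515 genes higher and 306 to 885 lower (482 to 1514 and 306 to 828 at least 2-fold). In these fits the lone library of a group is assumed to vary like the other group. The cause of the shifts with scaling, filter, FPKM values or a reseeded library left out was not tested. That of the day 7 libraries is weighed among the other observations. With the length trend removed, 781 genes were higher and 758 lower, and 1263 of the 1339 called genes were called in the same direction. With the replicate number as a block 811 genes were higher and 648 lower. Libraries with the same number did not deviate together across genes (correlation -0.05), which does not exclude a shared culture or day. Their numbers were not taken as pairs. No gene called with all 4 libraries changed direction under any of the 20 alternatives that tested it. In every one of these genes the groups did not overlap, so a change of direction was unlikely from the start. The 4 genes given by identifier kept their side of the threshold in 74 of 80 values. The list tests fixed before the data were examined were not run because the lists hold symbols. Thinning all libraries to the smallest total gave 759 higher and 634 lower genes, so the unequal depth was not what set these counts.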

Other observations

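The tests of fragment length, of length bias of single libraries and of other splits of the libraries were chosen after the results they bear on had been seen, as was the comparison of intervals in the test of mixed cells.

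Longer genes were higher and shorter genes lower at 2 h after reseeding, by 0.0918 on the log2 scale per doubling of length (SE over genes 0.0055). The trend is small beside the called changes. Median log2 fold changes were -0.21 in the shortest and 0.17 in the longest quintile, and the smallest called change was 0.92. Removal of the trend could thus undo few calls, and 94.3% of the called genes were called in the same direction after it. This argues against the trend as the source of most gene calls and does not bear on the cause of the trend. Fragment length of the libraries stays open in part. In 4 of the 6 pairs of libraries the one with the shorter effective lengths, as longer fragments give, had fewer counts on short genes. The 2 pairs that went the other way both include day 7 replicate 2 (slope -0.0613 against day 7 replicate 1, and 0.0939 for reseeded replicate 1 against it). By size these slopes did not follow the difference in length: reseeded and day 7 replicate 2 differed by -0.97 nt with a slope of 0.142, and reseeded and day 7 replicate 1 by -14.5 nt with a slope of 0.0325. FPKM values, taken to be divided by the effective length of each library, kept a slope of 0.0802 between the groups (SE over genes 0.0051). This slope was measured on log2(FPKM + 0.1) of 11780 genes with a mean FPKM of at least 1. It argues against the part of a fragment length effect that such a division removes. Other effects of fragment length stay open. A length bias of single libraries stays open too, because the largest slope within a group was 0.0613 in size and those of the 4 pairs across groups ran from 0.03 to 0.14, and a difference between the groups in the length of their transcripts was not tested.

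XLOC loci were lower at 2 h after reseeding than Ensembl genes. Their length and expression level are argued against as the whole cause, since the median of XLOC loci lay 0.27 below that of 10000 random sets of Ensembl genes matched on both (-0.270, with the lowest matched set at -0.13 and XLOC loci at -0.31). Reads shared with overlapping genes, as far as counts that are not whole mark them, are argued against too, because the 834 XLOC loci with whole counts had a median of -0.328. Single libraries may account for the pattern: all 4 pairs across groups dropped, but against day 7 replicate 1 the drops (-0.167 and -0.213 for reseeded replicates 1 and 2) were smaller than the difference of 0.216 between the 2 day 7 libraries, while against day 7 replicate 2 they were larger (-0.462 and -0.463). A biological difference between the groups stays open and untested beside this.

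Without day 7 replicate 1 the test called 2400 genes, against 788 without day 7 replicate 2. In the genes that were lower at 2 h the median of log2(replicate 1 / replicate 2) at day 7 was -0.307, and in those that were higher it was 0.29, so replicate 1 leaned towards the reseeded libraries in both directions. Whether a share of reseeded cells was mixed into replicate 1 stays open. The higher genes gave a share of 6.85% (95% interval over genes 5.86% to 8.05%), and the lower genes would need 16.8% (13.2% to 18.7%). These shares cannot decide it, because the genes were called with both day 7 libraries. Mixing would part those libraries most in strongly rising genes, which could then lose their call and lower the share. The intervals cover genes and not libraries. The length trend between the day 7 libraries is argued against, since the ratio of the counts was 2.864 after its removal and 3.05 before. Another candidate explanation that stays open is that the day 7 cultures differed by degree in the same genes that respond to reseeding, which the 2 libraries cannot test.

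The 4 libraries can be split into 2 and 2 in 3 ways, which is too few for a share below 0.05. The split by group called 1339 genes and was the 1 split with that many. The highest of the other splits called 0 genes in edgeR and 0 in limma voom, with at most 47 genes at an unadjusted p below 0.05 in edgeR. Each of these splits puts a reseeded and a day 7 library on either side. Any difference between the groups then counts as spread within a side, so few calls were likely from the start. The contrast with 1339 is therefore no measure of how many genes would be called without a group difference.

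FPKM summed to 952635 in day 7 replicate 2, against 809868 in day 7 replicate 1, 815895 in reseeded replicate 1 and 829959 in reseeded replicate 2.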
